A study of Mus musculus with 24 samples.

How the data were processed

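Gene expression was measured in 3 tissues of male mice of 2 inbred strains, the obese and diabetes-prone New Zealand Obese strain (NZO) and the lean C57BL/6 strain (B6). The tissues were gonadal white fat (gWAT), brown fat (BAT) and muscle of the skeleton. Per the labels' protocols the mice received a diet with 45% fat up to week 6, which the extraction notes give as an age; the age at its start is not given. Total RNA was extracted with TRIzol, and samples were selected for a high RNA integrity number before labelling with the green dye Cy3. The labels give 6 groups of 4 arrays, 24 arrays in all, each array holding 1 labelled RNA. A sample was placed in its group by the strain and tissue in its labels and is named here by the number in its title. The labels do not say whether these samples came from separate animals, so p-values measure only the spread between samples labelled as separate, which may in part be technical.

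Each array file held the spot intensities of a single-colour Agilent mouse array with probes of 60 bases. Per the file headers, the authors' scans were read with Agilent Feature Extraction 11.0.1.1, and the submitters' processing notes name version 9.1 of the same program; the cause of this difference was not settled. The processed intensity used here was background-subtracted and detrended within each array by that program, per the file headers, and was not scaled between arrays. Other flags used here, per the file headers, mark whether a spot was well above background, saturated or an outlier among its pixels. The deposited table of the whole series held, for each transcript identifier, the mean of the median spot intensity over the spots of that identifier. This was found by comparing it with the scanner files, where all 37877 values of each array agreed within a relative tolerance of 0.0001. Its values were therefore on a linear scale, not background-subtracted and not centred. Its medians were 51.5, 51.5, 63 and 49.75 for NZO gWAT, 59.3, 57, 70 and 58 for B6 gWAT, 43, 46, 43 and 46 for NZO BAT, 45.2, 47, 44 and 45.0 for B6 BAT, 50.2, 48.5, 51 and 45 for NZO muscle, and 43.5, 51, 43.9 and 45.8 for B6 muscle. These series values were used only as an alternative.

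Each array had 59305 spots other than controls, covering 55681 probes, of which 432 were spotted more than once and averaged. A gene name was taken from the RefSeq table of the mouse assembly GRCm38.p6 through the transcript accession for 27656 probes, and 28025 probes kept the name in the file; 1711 names changed in this way. These probes carried 34947 names, 11084 of them with several probes. Probe positions are those of the files, on the mouse build mm9, and no coordinate was taken from the RefSeq table. The percentage of probes well above background ranged from 52.9 to 60.4 (median 57.8), and no pair among the 276 pairs of arrays had a correlation above 0.999. The number of arrays limits the precision, with a median standard error of a log2 strain difference of 0.168 in gWAT, 0.150 in BAT and 0.194 in muscle. The probes were not compared with an NZO genome, so a sequence difference under a probe remains possible for any gene. This holds where 1 strain gave little or no signal and also where both strains were well above background.

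Values were log2 processed signals minus the 75th percentile of the array. A probe was tested in a tissue if it was well above background on all 4 arrays of at least 1 strain there, and the probe with the highest mean over the 24 arrays stood for its gene. Strain differences, NZO minus B6, were fitted in each tissue separately with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with data.table (version 1.17.8) for reading, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Differences of the strain effect between tissues were fitted over all 24 arrays with limma. Every adjusted p for a gene comes from these limma fits. Means are given with SD over 4 arrays, and log2 differences with the standard error (SE) of the fit. Where a gene was well above background on all arrays of 1 strain and on none of the other, the text gives a bound in place of a fold, if no other probe of the gene was well above background in the dimmer strain and the brighter mean exceeded the floor below. Fitted differences of such genes still entered the tests between tissues and the plot of shared genes, where they do not measure size. Genes well above background on 1 or 2 arrays of the dimmer strain are given by direction only, unless said otherwise. For the bound, the brighter strain's mean was divided by the dimmer strain's mean of, per array, the higher of the probe's own signal and the lowest signal among probes well above background. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.

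Gene lists and marker lists were fixed before the data were examined, as were the comparisons, the alternatives and the rule for named genes. The pathway lists were thermogenic programme, de novo lipogenesis, triglyceride storage and lipolysis, fatty acid oxidation, respiratory chain and ATP synthase, citric acid cycle, insulin signalling and glucose uptake, glycolysis, adipokines, inflammatory mediators, interferon response, p200 interferon-inducible family, major histocompatibility complex (MHC) and antigen presentation, extracellular matrix, unfolded protein response, antioxidant and glutathione, slow muscle fibre, fast muscle fibre, cell cycle, circadian clock and cholesterol synthesis. The marker lists were mature adipocyte, macrophage, T cell, B cell, neutrophil, mast cell, endothelial cell, fibroblast and adipocyte progenitor, mural cell, skeletal muscle fibre, mesothelium, epididymis, Schwann cell, erythroid cell and lymph node stroma. Each list with at least 3 tested members was tested with limma's camera at a preset correlation of 0.01 between genes, two-sided, with Benjamini-Hochberg adjustment over the lists of the tissue. Camera with an estimated correlation and fry were alternatives. For every called list the median, the mean and the test had the same sign; they differed in sign for 6 lists in gWAT, 8 in BAT and 7 in muscle that were not called.

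The rule for named genes took, per tissue and among called genes with a gene symbol that were above background on all 8 arrays and whose strains did not overlap, the 6 highest and the 6 lowest differences. It added the 3 largest bounds per direction, the 3 called members with the smallest adjusted p of each called list and up to 2 of the other lists. It further took the 5 genes per direction with the largest smallest difference over the 3 tissues and the 3 per direction with the smallest adjusted p for each difference between tissues. Ifi202b, Nnt, Lep, Adipoq, Ucp1 and Ppargc1a were always given. Members of lists named beyond these were chosen after their values were seen, and this is said where they appear. Not every gene that the rule took is printed.

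The steps were tested on simulated data. Of 100 genes changed 2-fold, 52 were recovered in gWAT, 62 in BAT and 48 in muscle; of 100 changed 4-fold, 82, 83 and 79. For differences between tissues, 41 and 81 were recovered for BAT against gWAT, 59 and 80 for muscle against gWAT, and 39 and 70 for BAT against muscle. Only the genes counted here were changed in each simulation, and all other genes had no strain difference. In the real gWAT data 31.2% of genes were called, so these rates do not give the recovery in the real comparisons. The alternatives covered the background correction (normexp with an offset of 50), the scaling (quantile, centring on the median), the deposited table, the filter on dim probes, the choice of probe, the samples in the fit, slide and scan as blocks, the replicate number as a block, array weights, robust fitting, a stricter threshold of 0.01, a minimum change of 2-fold, and leaving out each array. The arrays lay on 6 slides in 3 scans. Both strains of a tissue shared a slide on slides 4 and 6 for gWAT, slide 3 for BAT and slide 4 for muscle, and values within those slides were computed. Control spots and spots marked as outliers were left out, and saturated spots were kept. No sample and no column of sample values was left out of the main comparisons.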

Results

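Expression was profiled in gonadal white fat, brown fat and skeletal muscle of male NZO and B6 mice on a high-fat diet, to find how an obese, diabetes-prone strain differs in these tissues from a lean, diabetes-resistant one. NZO (New Zealand Obese) mice become obese on such diets, and B6 is the common C57BL/6 laboratory strain. Each of the 6 groups of strain and tissue held 4 single-colour arrays. The 75th percentile of the processed signal ranged from 238 to 360 units in gWAT, from 134 to 178.0 in BAT and from 143 to 235 in muscle. Arrays of the same strain and tissue correlated more closely across probes than arrays of different strains in gWAT (0.975 to 0.991 against 0.940 to 0.959) and BAT (0.974 to 0.991 against 0.943 to 0.970). In muscle the ranges overlapped (0.958 to 0.989 against 0.942 to 0.975). Levels below are log2 signals relative to the 75th percentile of the array, as mean ± SD over 4 arrays, and differences are NZO minus B6.

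**Figure D1:**
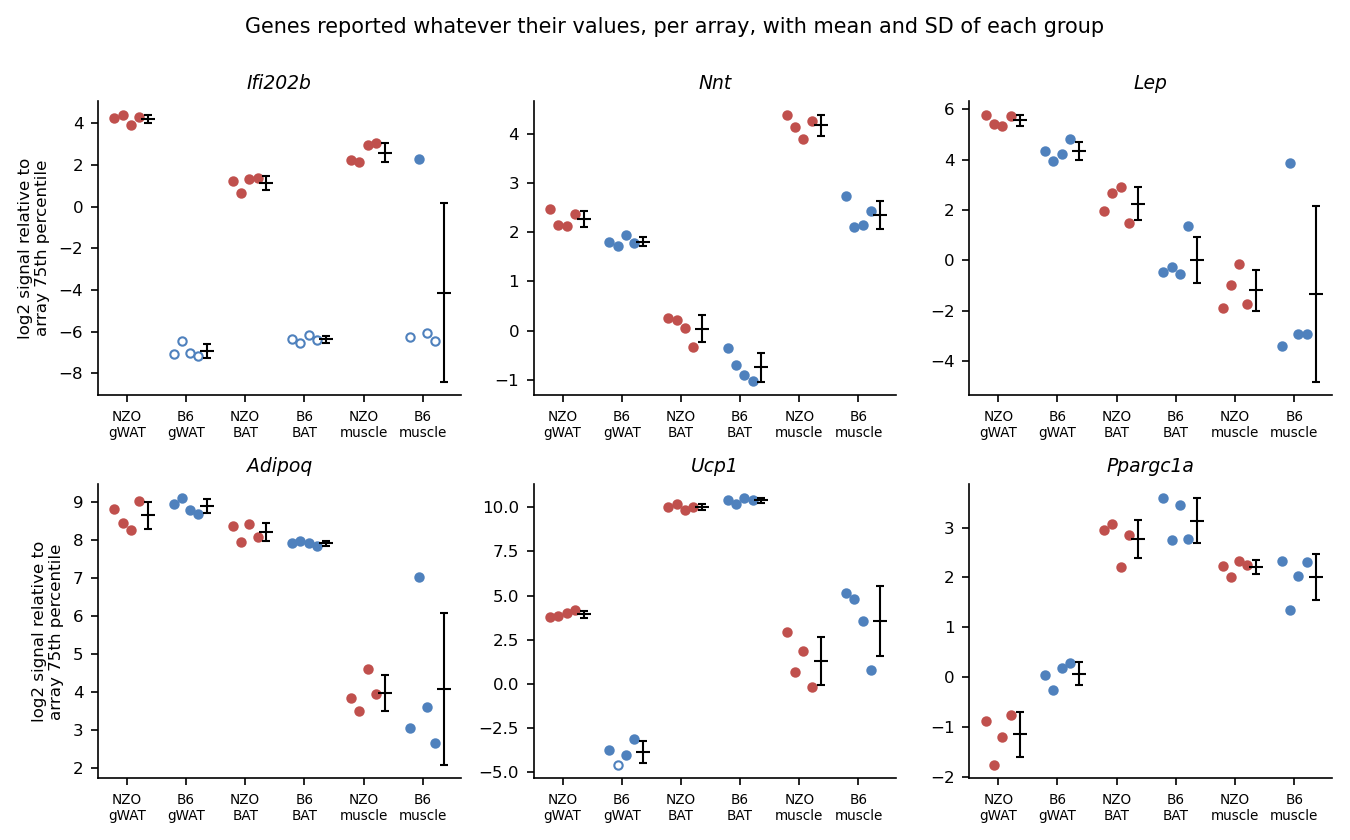
Log2 signal relative to the array's 75th percentile for Ifi202b, Nnt, Lep, Adipoq, Ucp1 and Ppargc1a in each of the 24 arrays (NZO red, B6 blue, open symbols not well above background), with mean and SD per group of 4. Ifi202b was near -6.94 in B6 gWAT and 4.21 in NZO gWAT, and a single B6 muscle array lay at 2.30 for Ifi202b and at 3.87 for Lep.

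More genes were called in white fat than in the other tissues, with most macrophage, inflammatory and cell cycle genes tested and some brown-fat genes higher in NZO, and 7 of 17 lipogenic genes lower. Ifi202b, a p200-family gene within an obesity locus known from NZO crosses (probe on mm9 chromosome 1, 175892953 to 175893982), was at 4.21 ± 0.21 in NZO and not well above background on any B6 array, at least 531-fold higher (adjusted p = 5.10e-08). Lep, which encodes the satiety hormone leptin (chromosome 6, 29023234 to 29023293), was 2.36-fold higher in NZO (5.57 ± 0.22 against 4.33 ± 0.36, adjusted p = 0.00223). Ucp1, the uncoupling protein of brown fat (chromosome 8, 85821788 to 85821847), was at 3.95 ± 0.19 in NZO and -3.86 ± 0.62 in B6, a difference of 7.82 (SE 0.29, adjusted p = 1.46e-06). Ppargc1a, a coactivator of mitochondrial biogenesis, was lower in NZO by contrast, with a difference of -1.21 (SE 0.23, adjusted p = 0.00530). Adipoq, the adiponectin gene, did not pass the test (difference -0.24, SE 0.19, adjusted p = 0.353).

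Of 21662 genes tested in gWAT, limma called 6762 (31.2%), 3603 higher and 3159 lower in NZO, and 2750 of these differed at least 2-fold. Among genes with a symbol, measured on all 8 arrays and with no overlap of the strains, Tph2, an enzyme of serotonin synthesis, had the highest difference (6.66, SE 0.22). Atp1a4, a sodium pump subunit (5.91, SE 0.31), and Atp6v0d2, a proton pump subunit (5.34, SE 0.15), came next. Otop1, a proton channel of brown fat, followed at 5.21 (SE 0.18), Tox4 at 5.08 (SE 0.17, with -0.07 from another probe) and the macrophage glycoprotein gene Gpnmb at 5.05 (SE 0.29). The lowest were those of Snhg11, a non-coding RNA (-4.95, SE 0.26), Inmt, an amine methyltransferase (-4.68, SE 0.45), Cdsn (-4.19, SE 0.25), Orm3, an acute-phase gene (-4.01, SE 0.16), Alkal2 (-3.94, SE 0.16) and Klhdc9 (-3.85, SE 0.29). Adjusted p for these 12 genes was at most 0.000158. Ctnna2, a catenin gene, was at least 80.5-fold higher in NZO and H2-Ea-ps, an MHC class II pseudogene, at least 47.7-fold. Zfp979, Pole4, a DNA polymerase subunit, and Ttc8, a ciliary gene, were at least 75.2-fold, 55.1-fold and 46.1-fold lower, with no NZO array well above background.

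Of 15 macrophage markers, 13 rose in NZO, 1 fell and 1 did not pass (the same 13 and 1 adjusted over the list alone). Trem2, a receptor of lipid-associated macrophages, was 21.6-fold higher (5.38 ± 0.19 against 0.95 ± 0.21), Cd68 5.38-fold and Gpnmb 33.2-fold, while Itgam, named after its value was seen, was lower (-0.80, SE 0.25), a call that ended without any of the arrays but NZO 003 (adjusted p 0.0507 to 0.0995). Camera gave an adjusted p of 6.27e-08 for the list (adjusted p = 0.359 with an estimated correlation). Of 15 inflammatory mediators, 12 rose and 3 did not pass (13 rose and 1 fell adjusted over the list alone). The monocyte chemokine Ccl2 was 11.5-fold higher, and Il1rn, the interleukin-1 receptor antagonist, and Il6, both well above background on no B6 array, were at least 15.3-fold and 3.21-fold higher (camera adjusted p = 8.47e-06; adjusted p = 0.531 with an estimated correlation). Of 22 extracellular matrix genes, 16 rose, 1 fell and 5 did not pass (17 and 1 adjusted over the list alone). These included Col6a2, a collagen chain (2.74-fold), the protease inhibitor Timp1 (14.9-fold) and the proteoglycan Bgn (2.24-fold), with a camera adjusted p of 8.47e-06 (adjusted p = 0.593 with an estimated correlation). Dcn, named after its value was seen, was lower (-0.48, SE 0.16), a call that ended without any of the arrays but NZO 007 (adjusted p 0.0595 to 0.127). Of 5 B cell markers, Cd22 and Cd79a rose, by 1.93 (SE 0.17) and 1.93 (SE 0.25), and 3 did not pass (3 rose adjusted over the list alone). That list's adjusted p was 0.0459 (adjusted p = 0.681 with an estimated correlation), 0.0522 with slide as a random block, and 0.0618 and 0.0747 without B6 replicate 015 or 009.

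Of 19 cell cycle genes, 17 rose in NZO gWAT and 2 did not pass, the same 17 adjusted over the list alone. Mcm3, a replicative helicase subunit, was 3.23-fold higher, Birc5, a mitotic gene, 3.95-fold, and Rrm2, a ribonucleotide reductase subunit, 2.94-fold (camera adjusted p = 6.17e-11; adjusted p = 0.359 with an estimated correlation). Another Mcm3 probe gave a log2 difference of 0.03 (adjusted p = 0.893). Of 13 genes of the unfolded protein response, 7 rose and 6 did not pass (8 rose adjusted over the list alone). The stress factor Atf3 was 8.75-fold higher, Sdf2l1 3.06-fold and the chaperone Hspa5 1.62-fold (camera adjusted p = 0.00402; adjusted p = 0.576 with an estimated correlation).

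Metabolic groups split by direction. Of 17 genes of de novo lipogenesis, the making of fatty acids from sugar, 7 fell in NZO gWAT, 1 rose and 9 did not pass (9 fell and 1 rose adjusted over the list alone). The desaturases Fads1 (-1.54, SE 0.12) and Scd1 (-1.04, SE 0.11) and the carboxylase Acaca (-1.87, SE 0.18) were lower, and Elovl5, named after its value was seen, was higher (0.58, SE 0.13; camera adjusted p = 0.000899; adjusted p = 0.681 with an estimated correlation). Of 18 thermogenic genes, 9 rose, 2 fell and 7 did not pass (10 and 2 adjusted over the list alone). Otop1, Ucp1 and the muscle-type carnitine transferase Cpt1b (9.34-fold) were higher, Ppargc1a was lower, and so was the adrenergic receptor gene Adrb3, named after its value was seen (-1.69, SE 0.27). Camera gave adjusted p = 0.00200 for this list (adjusted p = 0.593 with an estimated correlation). Brown-fat transcripts were abundant in BAT itself, where Ucp1 stood at 10.38 ± 0.14 in B6. With the 942 genes at least 4-fold higher in NZO BAT than in B6 gWAT left out, an alternative chosen after the data were seen, 6435 genes were called. This left 3 of the 18 thermogenic genes, so it does not test that list, and 4 of the 5 B cell markers (without Cd22), whose list no longer passed (median 1.93 with and without, adjusted p = 0.214). The genes left out were chosen between tissues of different strains, so a strain difference can also place a gene among them.

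The other lists did not pass camera in gWAT with the settings chosen as main. Under alternatives the respiratory chain (quantile normalization, adjusted p = 0.0148; adjusted p = 0.994 with an estimated correlation), lymph node stroma (fry, 0.0497; adjusted p = 0.985 with an estimated correlation) and mesothelium (without B6 replicate 010, 0.0189; adjusted p = 0.985 with an estimated correlation) did. Among pathways, 4 genes rose and 2 fell of 22 in triglyceride storage and lipolysis, including the lipid droplet genes Plin5 (2.08, SE 0.24) and Plin2 (1.74, SE 0.22), and 5 rose and 1 fell of 23 in fatty acid oxidation. Of 30 respiratory chain genes limma called 0, with 2 higher and 2 lower at an unadjusted p under 0.05. In the citric acid cycle 2 rose and 1 fell of 15. In insulin signalling and glucose uptake 3 rose and 7 fell of 24, including glycogen synthase Gys1 (-1.20, SE 0.16) and the receptor substrate Irs1 (-0.96, SE 0.17). In glycolysis 4 rose and 6 fell of 18. In MHC and antigen presentation 3 rose, among them B2m (0.91, SE 0.12), and 1 fell of 16, and in cholesterol synthesis 2 rose and 1 fell of 19. The muscle fibre lists had 2 higher and 1 lower of 6 (slow), 1 and 2 of 9 (fast) and 1 and 1 of 6 (skeletal muscle fibre). Adjusted over the list alone, the counts of these lists differed only for insulin signalling (3 and 8) and glycolysis (6 and 6). Among cell type markers, 2 rose and 1 fell of 8 for mature adipocytes (2 and 2 adjusted over the list alone), 1 and 1 of 8 for T cells (1 and 0), and 2 and 1 of 5 for mast cells (3 and 1). Fibroblasts and progenitors had 2 higher and 1 lower of 7, mural cells 0 and 1 of 7, endothelial cells 0 and 1 of 9 (0 adjusted over the list alone), and lymph node stroma 1 and 0 of 5 (1 and 1). Limma called 0 of 7 mesothelial markers (3 lower at an unadjusted p under 0.05) and 0 of 5 erythroid markers (0 unadjusted).

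With slide as a fixed block over all arrays, 6471 genes were called in gWAT. Slides 4 and 6 held both strains of gWAT, and the medians of the called lists there were 1.00 and 1.87 for the thermogenic programme, -1.20 and -0.33 for lipogenesis, 1.41 and 1.30 for inflammatory mediators, 0.91 and 0.58 for extracellular matrix, 0.59 and 0.56 for the unfolded protein response, 1.07 and 1.45 for cell cycle, 1.79 and 1.63 for macrophages, and 1.53 and 1.66 for B cells. In that fit with slide as a block, Lep no longer passed (0.98, adjusted p = 0.608, against a difference of 1.24 in the fit of gWAT alone). The fit with slide takes its spread from the arrays of all tissues, the muscle array B6 011 among them. Lep had an SD of 3.49 in B6 muscle, against 0.22 in NZO gWAT and 0.36 in B6 gWAT. The lost call of Lep therefore does not separate an effect of slide from this wider spread. Centring arrays on the median moved the median difference of all genes from 0.02 to 0.28, and with it 4611 genes were higher and 1540 lower, against 3603 and 3159 (53.3% higher). The gene Nnt, encoding the mitochondrial transhydrogenase, was higher by 0.46 (SE 0.12, adjusted p = 0.0180), but another probe gave -2.06 (adjusted p = 0.0146), so its direction in gWAT is open; without B6 replicate 010 or 011 the adjusted p was 0.0534 or 0.0563.

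Muscle transcripts were abundant in brown fat of B6 and far lower in that of NZO, while 11 of 18 cell cycle genes were higher and 9 of 18 glycolytic genes lower in NZO. Tnnc2, the fast troponin C, was at 6.87 ± 0.85 in B6 and -0.06 ± 0.99 in NZO, and Acta1, skeletal actin, at 5.89 ± 0.83 and -1.15 ± 1.48. Ucp1 was high in both strains, at 10.38 ± 0.14 in B6. Its strain difference of -0.38 (SE 0.11) did not pass (adjusted p = 0.0623), and did so without NZO replicate 011 (-0.44, adjusted p = 0.0462) or B6 replicate 011 (-0.44, adjusted p = 0.0485). Ifi202b was at least 39.7-fold higher in NZO BAT (1.15 ± 0.34, no B6 array well above background, adjusted p = 4.71e-07), and Lep was 4.71-fold higher (adjusted p = 0.0169). Nnt was at 0.05 ± 0.27 in NZO and -0.74 ± 0.29 in B6 (difference 0.79, SE 0.18, adjusted p = 0.0225), a call that ended without NZO replicate 009, 011 or 003 or B6 replicate 011, 015 or 009 (adjusted p 0.0515 to 0.0702), with arrays centred on the median (0.0507) and without the filter on dim probes (0.0529). Adipoq (0.29, SE 0.12, adjusted p = 0.168) and Ppargc1a (-0.37, SE 0.26, adjusted p = 0.405) did not pass.

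Limma called 3138 of 20811 genes in BAT (15.1%), 1579 higher and 1559 lower in NZO, 1362 of them at least 2-fold. Without NZO replicate 009, 993 were higher. Among genes with a symbol, measured on all 8 arrays and with no overlap of the strains, Gchfr, a regulator of biopterin synthesis, had the highest difference (4.72, SE 0.28). Tox4 (4.55, SE 0.17, with -0.18 from another probe), the transcription factor Olig1 (4.27, SE 0.15) and Tmem45a (4.19, SE 0.33) followed. Then came Prom1, a membrane protein gene of progenitor cells (4.15, SE 0.35), and the small GTPase Rem1 (3.80, SE 0.25). Among the same genes the lowest differences were all of muscle genes, namely the perinatal myosin Myh8 (-8.71, SE 1.03), Tnnt3 (-7.76, SE 0.67), Tnni2 (-7.50, SE 0.71), Acta1 (-7.05, SE 0.73), Tnnc2 (-6.93, SE 0.56) and the sarcomere gene Tcap (-6.35, SE 0.66). Adjusted p for these 12 genes was at most 0.000931. Olfr224, an olfactory receptor gene, was at least 27.2-fold higher in NZO. Ckmt2, mitochondrial creatine kinase, Zfp982 and the sarcomere gene Myot were at least 71.4-fold, 39.5-fold and 38.3-fold lower.

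All 10 fast muscle fibre genes tested and all 8 skeletal muscle fibre markers fell in NZO BAT, also adjusted over the list alone, with medians of -7.18 and -7.46. Pvalb, the fast-fibre calcium buffer parvalbumin, was lower by 5.62 log2 units (SE 0.37), and the calcium store gene Casq1, not well above background in NZO, was at least 27.9-fold lower. Camera gave 2.41e-12 and 1.32e-09 (adjusted p = 0.362 with an estimated correlation for both). The lists share 6 members. Of 18 glycolytic genes, 9 fell and 9 did not pass (14 fell adjusted over the list alone), among them the muscle isoform Pgam2 (-6.27, SE 0.45), Pgk1 (-0.89, SE 0.11) and Pkm (-1.36, SE 0.17; camera adjusted p = 7.17e-08; adjusted p = 0.362 with an estimated correlation). Another Pgk1 probe gave -0.19 (adjusted p = 0.292). With 1336 genes at least 4-fold higher in NZO muscle than in NZO BAT left out, chosen after the data were seen, limma called 2649 genes (1479 higher and 1170 lower). Glycolysis still passed camera at the preset correlation with 13 of its 18 genes left (median -0.57, against -0.62 with all, adjusted p = 3.70e-05). The genes left out were chosen partly by their level in NZO BAT, 1 side of this comparison, so this result is not independent of it.

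Of 18 cell cycle genes, 11 rose in NZO BAT and 7 did not pass (14 adjusted over the list alone). Birc5 was 3.50-fold and Mcm3 2.34-fold higher, and Cdk1, the mitotic kinase, was well above background on all NZO arrays and no B6 array (camera adjusted p = 5.61e-08; adjusted p = 0.362 with an estimated correlation). Another Mcm3 probe ran the other way (log2 difference -0.43, adjusted p = 0.0431), so that gene's direction in BAT is open. Of 10 inflammatory mediators, 4 rose and 6 did not pass, the same 4 adjusted over the list alone, with Tnf at least 2.60-fold and the adhesion gene Vcam1 1.59-fold higher (camera adjusted p = 0.0205; adjusted p = 0.484 with an estimated correlation). Without NZO replicate 007 or B6 replicate 015 the list's adjusted p was 0.0658 or 0.0621. Ccl2 was 2.38-fold higher (adjusted p = 0.0178, and 0.0522 without NZO replicate 009 and 0.0521 without NZO replicate 003).

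Of 20 thermogenic genes, 5 fell in NZO BAT and 15 did not pass (6 fell adjusted over the list alone). The coactivator Ppargc1b was lower by 1.21 log2 units (SE 0.19) and the fat-secreted Bmp8b, well above background on 1 NZO array, was lower too (camera adjusted p = 0.0102; adjusted p = 0.562 with an estimated correlation). Of 17 lipogenic genes, 3 fell and 14 did not pass (4 adjusted over the list alone), namely Me1 (-1.48, SE 0.37), Scd1 (-1.40, SE 0.36) and Acaca (-1.06, SE 0.30; camera adjusted p = 0.00457; adjusted p = 0.802 with an estimated correlation). Leaving out NZO replicate 009 or any B6 array ended each of these 3 calls, and NZO replicate 011 also that of Scd1 (adjusted p 0.0530 to 0.0758 for Me1, 0.0546 to 0.0888 for Scd1 and 0.0788 to 0.124 for Acaca). Of 23 genes of fatty acid oxidation, 3 fell and 20 did not pass (4 adjusted over the list alone), including the dehydrogenase Acadl (-0.75, SE 0.10; camera adjusted p = 0.00487; adjusted p = 0.511 with an estimated correlation). With slide as a fixed block, the thermogenic, oxidation and inflammatory lists no longer passed (adjusted p = 0.0556, 0.241 and 0.468), mural cell markers did (adjusted p = 0.00841; in the fit without slide, adjusted p = 0.848 with an estimated correlation), and 1767 genes were called in BAT. The lipogenic list did not pass with slide as a random block (adjusted p = 0.115) or with fry (0.107), nor the oxidation list under quantile normalization (0.125).

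The other lists did not pass camera in BAT with the settings chosen as main. Under alternatives the respiratory chain passed without NZO replicate 009 or B6 011 (adjusted p = 0.0480 and 0.0181; adjusted p = 0.848 with an estimated correlation), and so did slow fibre without B6 011 (0.0354; adjusted p = 0.848 with an estimated correlation). Cholesterol synthesis did without NZO 011 (0.00868; adjusted p = 0.848 with an estimated correlation), mast cells without B6 010 (0.0486; adjusted p = 0.758 with an estimated correlation), and B cells and lymph node stroma with fry (0.0104 and 0.0374; adjusted p = 0.848 with an estimated correlation for both). Neutrophils did with fry, with slide as a random block and without B6 010 (0.00267, 0.00296 and 0.0437; adjusted p = 0.758 with an estimated correlation). Triglyceride storage had 3 higher and 1 lower of 22, the citric acid cycle 1 and 2 of 15 (2 and 4 adjusted over the list alone), insulin signalling 2 and 2 of 24, and cholesterol synthesis 2 and 1 of 19. Limma called 0 of 30 respiratory chain genes (6 lower at an unadjusted p under 0.05; camera adjusted p = 0.0605). In MHC and antigen presentation 2 rose and 3 fell of 16 (2 and 4 adjusted over the list alone), with the class II gene H2-Ab1 at -2.03 (SE 0.15). Extracellular matrix had 2 and 2 of 22 (3 and 2), the unfolded protein response 0 and 1 of 13 (0 adjusted over the list alone) and slow fibre genes 0 and 3 of 8 (0 and 5). Limma called 0 of 13 circadian genes (0 unadjusted). Marker lists gave 2 higher and 0 lower of 8 for mature adipocytes, 1 and 1 of 14 for macrophages (2 and 1), 0 and 1 of 7 for T cells (0 and 2), 1 and 0 of 4 for B cells, 0 and 1 of 4 for neutrophils, 1 and 0 of 9 for endothelial cells, 0 and 1 of 6 for fibroblasts, 0 and 3 of 7 for mural cells (0 and 4), and 1 and 0 of 4 for lymph node stroma. Limma called 0 of 5 mast cell markers (2 higher unadjusted, and 2 adjusted over the list alone), 0 of 5 Schwann cell markers (1 higher and 1 lower unadjusted) and 0 of 5 erythroid markers (0 unadjusted). On the slide that held both strains of BAT, 1 array each, list medians were -8.10 for skeletal muscle fibre, -7.61 for fast fibre, -0.65 for glycolysis, 0.89 for cell cycle, 1.00 for inflammatory mediators, -0.46 for the thermogenic programme, -0.40 for lipogenesis and -0.23 for fatty acid oxidation.

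**Figure D2:**
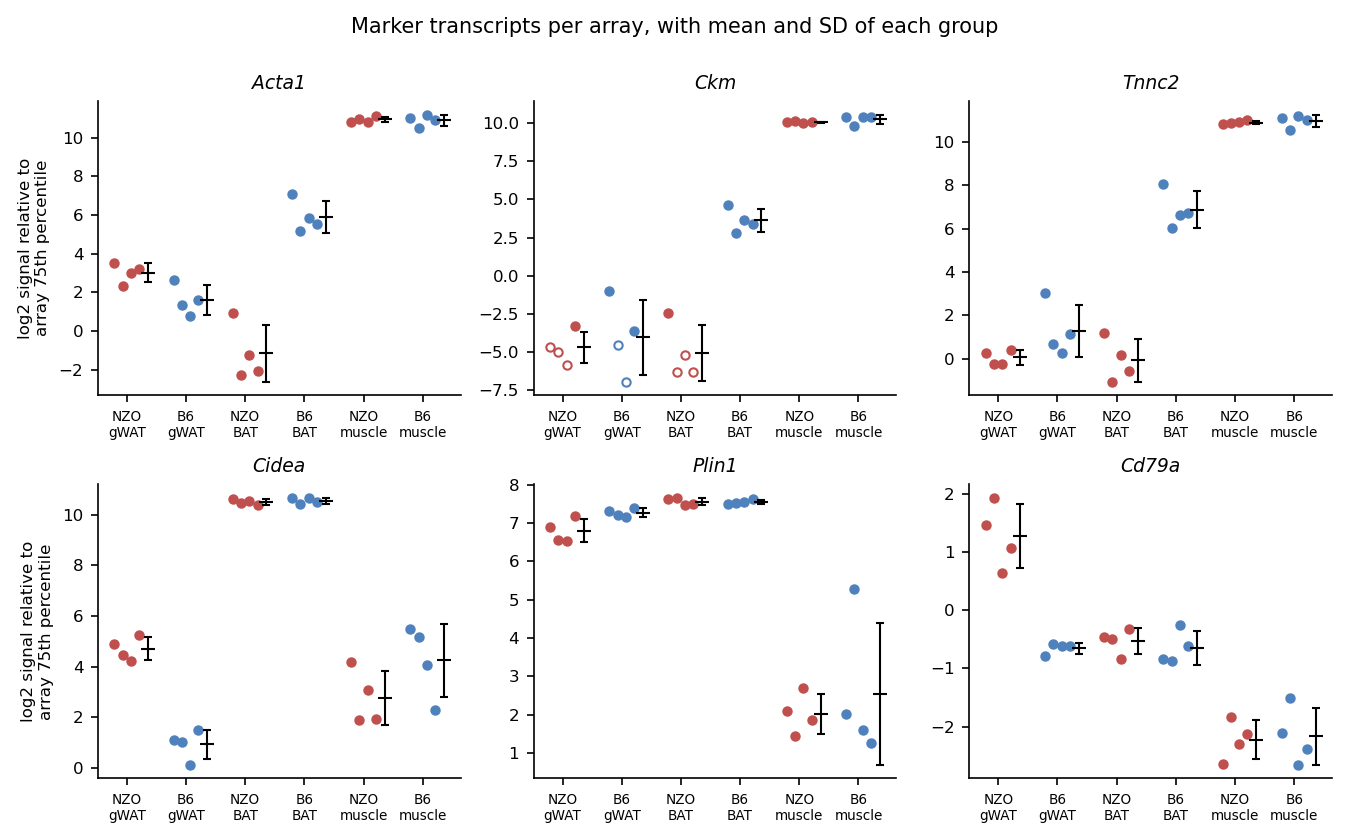
Log2 signal relative to the array's 75th percentile of the muscle genes Acta1, Ckm and Tnnc2, the fat genes Cidea and Plin1 and the B cell gene Cd79a in each of the 24 arrays (NZO red, B6 blue, open symbols not well above background), with mean and SD per group of 4. Tnnc2 was at 6.87 in B6 BAT and at -0.06 in NZO BAT, and Cidea at 4.70 in NZO gWAT and 0.93 in B6 gWAT.

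In skeletal muscle, Nnt and 3 of 5 mast cell markers were higher in NZO, and the class II genes H2-Ab1 and H2-Aa were lower. Nnt was 3.53-fold higher (4.17 ± 0.21 against 2.35 ± 0.29, log2 difference 1.82, adjusted p = 0.000752), and another probe gave a log2 difference of 2.63. H2-Ab1, a class II chain gene, was lower by 2.43 log2 units (SE 0.21, adjusted p = 0.000440). The library labelled B6 replicate 011 stood apart from the other B6 muscle libraries, with Lep at 3.87 (next highest -2.92), Adipoq at 7.02 and Ifi202b at 2.30 (next highest -6.06). Ifi202b, at 2.60 ± 0.47 in NZO, therefore did not pass (adjusted p = 0.0805), and passed without that library, where no B6 array was well above background and the gene was at least 99.8-fold higher (adjusted p = 8.20e-06). Lep likewise went from 0.16 (SE 1.51, adjusted p = 0.974) to 1.90 (SE 0.43, adjusted p = 0.0340). Adipoq (-0.10, SE 0.87, adjusted p = 0.970), Ppargc1a (0.20, SE 0.22, adjusted p = 0.720) and Ucp1 (-2.26, SE 1.01, adjusted p = 0.303) did not pass. Ucp1 varied between arrays of both strains, from 0.81 to 5.14 in B6 and from -0.17 to 2.94 in NZO. Cidea, also of the thermogenic programme, ran from 2.28 to 5.47 in B6 and from 1.90 to 4.16 in NZO. The liver transcript Alb also varied, from -2.19 to 3.85 in B6 muscle and from -0.03 to 5.44 in NZO muscle. In gWAT it ran from -1.23 to 4.92 in B6 and from -0.25 to 4.91 in NZO. Mup1, Ttr, Apoa1, Serpina1a and Fgb are also liver transcripts. In muscle and gWAT of each strain they were lowest and highest on the same arrays as Alb. The source of these liver transcripts was not tested.

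Limma called 1072 of 20873 genes in muscle (5.14%), 492 higher and 580 lower in NZO, 681 of them at least 2-fold. Without B6 replicate 011 it called 2164 (926 higher and 1238 lower), 1048 of the 1072 among them, and without NZO replicate 003, NZO 007, B6 010 or B6 009 it called 671, 654, 607 and 668. The lower count was 375 and 381 without NZO 011 and B6 015. The highest differences were those of the vesicle sensor gene Syt10 (6.45, SE 0.22), the chemokine gene Ccl19 (5.10, SE 0.27), the opsin gene Opn1mw (4.93, SE 0.26), Tox4 (3.72, SE 0.46), the neuropeptide receptor gene Vipr2 (3.56, SE 0.18) and Ifit1bl2 (3.43, SE 0.16). Among the same genes the lowest differences were those of the securin gene Pttg1 (-4.89, SE 0.23), the acetylcholine receptor gene Chrna9 (-4.28, SE 0.29), the trafficking gene Rab6b (-4.25, SE 0.25), the T cell receptor partner Cd28 (-3.61, SE 0.25), Tmsb15b1 (-3.18, SE 0.23) and Samd4 (-3.16, SE 0.22). Adjusted p for these 12 genes was at most 0.00400. Another Chrna9 probe gave 2.38 (adjusted p = 0.00508), so that gene's direction is open. Methig1, Calm4 and Higd1c were at least 32.9-fold, 11.6-fold and 8.78-fold higher, and Pole4, Apol10b and Ttc8 at least 20.6-fold, 18.0-fold and 13.1-fold lower.

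Of 5 mast cell markers, 3 rose in NZO muscle and 2 did not pass (5 rose adjusted over the list alone), including the mast cell proteases Tpsb2 (1.15, SE 0.17), Cpa3 (1.34, SE 0.22) and Cma1 (1.19, SE 0.28; camera adjusted p = 5.75e-05; adjusted p = 0.455 with an estimated correlation). The call of Cma1 ended without NZO replicate 011, 003 or 007 or B6 replicate 011, 015 or 009 (adjusted p 0.0593 to 0.129). Of 4 lymph node stroma markers, Ccl19, a lymphocyte attractant, rose 34.4-fold and 3 did not pass (1 rose adjusted over the list alone; camera adjusted p = 0.00549; adjusted p = 0.455 with an estimated correlation). Of 22 extracellular matrix genes limma called 0, with 6 higher at an unadjusted p under 0.05 and 0 adjusted over the list alone (median 0.39, camera adjusted p = 0.00186; adjusted p = 0.838 with an estimated correlation). These 3 lists also passed without B6 replicate 011 (adjusted p = 0.000619, 0.00748 and 0.000260; adjusted p = 0.846, 0.685 and 0.880 with an estimated correlation). So did cell cycle genes (3 rose, median 0.81, adjusted p = 0.000619; adjusted p = 0.880 with an estimated correlation) and inflammatory mediators (2 rose, median 0.54, adjusted p = 0.0391; adjusted p = 0.846 with an estimated correlation), which did not pass with it. With fry the matrix list did not pass (adjusted p = 0.350). On slide 4, which held 1 array of each strain, the medians of mast cells, lymph node stroma and matrix were 1.32, 1.41 and 0.97.

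The other 5 lists that passed in muscle did so only with B6 replicate 011 included. Of 16 genes of MHC and antigen presentation, 3 fell and 13 did not pass (6 fell adjusted over the list alone), namely H2-Ab1, H2-Aa (-2.00, SE 0.28) and H2-DMb1 (-1.51, SE 0.28; camera adjusted p = 0.000431; adjusted p = 0.838 with an estimated correlation). The list's adjusted p was 0.134 without that library, and its median of -0.47 was 0.07 on slide 4. H2-DMb1 lost its call without NZO replicate 009 or 011 or B6 replicate 010 (adjusted p = 0.0507, 0.0583 and 0.0530). Of 21 interferon response genes, 3 fell and 18 did not pass (6 adjusted over the list alone), among them the antiviral gene Mx2, at least 5.13-fold lower (camera adjusted p = 0.00193, 0.196 without that library; adjusted p = 0.838 with an estimated correlation). Insulin signalling had 2 lower of 24, the same 2 adjusted over the list alone, among them the receptor substrate gene Irs2 (-0.90, SE 0.14; camera adjusted p = 0.0234, 0.103 without that library; adjusted p = 0.838 with an estimated correlation). Lipogenesis had 1 lower of 17, also adjusted over the list alone (camera adjusted p = 0.0396, 0.503 without that library; adjusted p = 0.838 with an estimated correlation). Of 18 genes of cholesterol synthesis limma called 0, with 2 lower unadjusted and 0 adjusted over the list alone (camera adjusted p = 0.0137, 0.409 without that library; adjusted p = 0.838 with an estimated correlation). The lipogenesis list also failed without NZO replicate 011 or 007 (adjusted p = 0.177 and 0.0751), the insulin list without NZO replicate 011 (0.0867) and the cholesterol list without NZO replicate 009 (0.0695). None of the 5 passed with fry (adjusted p 0.129 to 0.350), and interferon response, insulin signalling, lipogenesis and cholesterol synthesis did not with slide as a fixed block (0.603, 0.298, 0.309 and 0.442), the last 3 also not with it as a random block (0.0660, 0.103 and 0.0733). On slide 4 the medians were -0.02 for interferon response, -0.33 for insulin signalling, -0.41 for lipogenesis and -0.27 for cholesterol synthesis.

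The remaining lists did not pass camera in muscle with all 8 arrays and the settings chosen as main, cell cycle and inflammatory mediators among them. With all 8 arrays the respiratory chain (adjusted p = 0.00366) and the citric acid cycle (0.0252) passed under quantile normalization, each with adjusted p = 0.944 with an estimated correlation. The respiratory chain (0.0327), slow fibre (0.0193), antioxidant genes (0.0364) and endothelial cells (0.0478) passed with normexp, and endothelial cells (0.00772) and epididymis (0.0144) with slide as a fixed block. Without single arrays there passed antioxidant genes (NZO 003 or 007, B6 015 or 009; 0.0309, 0.0281, 0.0204 and 0.0216), slow fibre (NZO 003, B6 010 or 009; 0.0246, 0.00433 and 0.0195), epididymis (NZO 003; 0.0418), triglyceride storage (B6 015 or 009; 0.0200 and 0.00901) and the thermogenic programme (B6 009; 0.0118). These lists had adjusted p = 0.838 with an estimated correlation, triglyceride storage 0.935 and the respiratory chain 0.944. Antioxidant genes had 1 higher and 2 lower of 22 (1 and 3 adjusted over the list alone), glycolysis 0 and 1 of 18, fast fibre 1 and 0 of 10, B cells 1 and 0 of 4, neutrophils 0 and 1 of 5, mural cells 0 and 1 of 7, the p200 family 0 and 1 of 4 (1 and 1) and epididymis 1 and 0 of 3. Limma called 0 members of the thermogenic programme (2 of 17 lower at an unadjusted p under 0.05), fatty acid oxidation (2 of 23 lower), the citric acid cycle (1 of 15 higher), adipokines (1 of 11 lower), inflammatory mediators (2 of 9 higher), slow fibre (1 of 9 higher), macrophages (2 of 15 lower), T cells (1 of 5 lower), mature adipocytes (1 of 8 lower) and endothelial cells (2 of 9 higher). Cell cycle had 3 higher and 1 lower of 17 unadjusted, and circadian clock 3 and 1 of 13. It called 0, and 0 unadjusted, of 22 genes of triglyceride storage, 30 of the respiratory chain, 13 of the unfolded protein response, 7 fibroblast, 8 skeletal muscle fibre, 6 Schwann cell and 5 erythroid markers. Adjusted over the list alone, 1 thermogenic gene fell, 1 inflammatory mediator rose and 2 endothelial markers rose.

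**Figure D3:**
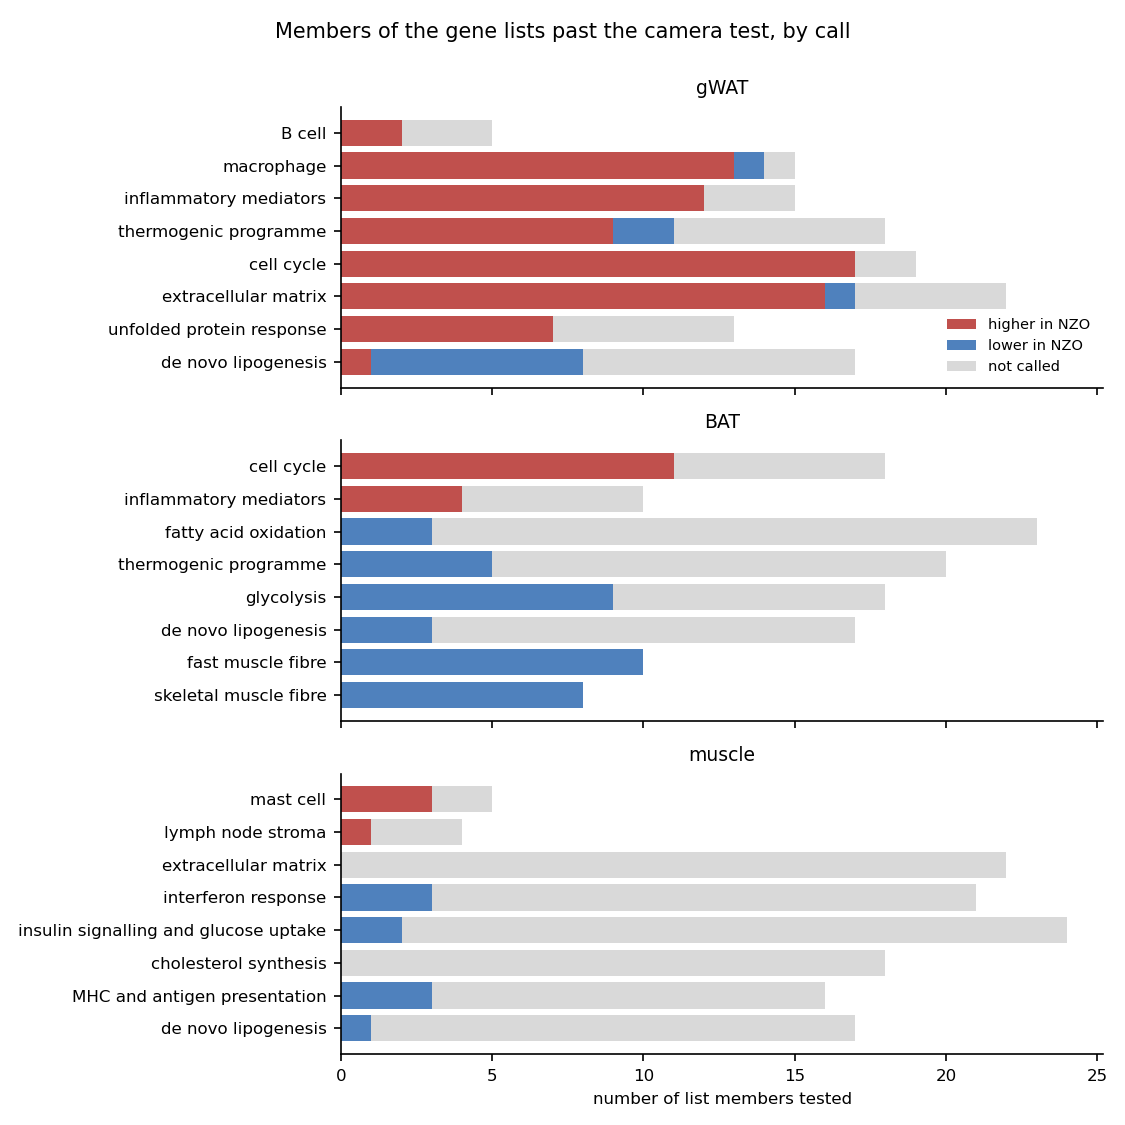
Number of tested members that were higher in NZO, lower in NZO or not called for each gene list that passed camera in gWAT, BAT and muscle, with 8 lists per tissue. In gWAT 17 of 19 cell cycle and 13 of 15 macrophage genes were higher, in BAT all 10 fast fibre genes were lower, and in muscle most members were not called.

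Whether the strain difference itself differed between tissues was tested over all 24 arrays. Ucp1 showed this most strongly among the genes always given. Its strain difference was smaller in BAT than in gWAT (-8.19, SE 0.95, adjusted p = 1.17e-05) and in muscle than in gWAT (-10.08, SE 0.95, adjusted p = 1.34e-06). All these fits take 1 spread from the 24 arrays, the muscle library B6 011 among them. Calls and ranks of genes high in that library depend on it. For BAT against gWAT, Ifi202b (-3.63, SE 1.67, adjusted p = 0.152) and Lep (1.00, SE 1.45, adjusted p = 0.702) did not pass. Between BAT and gWAT, 2895 of 19899 genes differed, 1470 with a larger and 1425 with a smaller value in BAT. The fitted differences of 1960 of them had opposite signs, whether or not the strain difference passed in either tissue. Genes called in both tissues with opposite directions numbered 189. Wnt5b, a secreted signalling factor, was higher in NZO BAT by 1.80 and lower in NZO gWAT (-0.98), a difference of 2.79 (SE 0.22), while Klhdc9 differed by 4.83 (SE 0.39) and Gstm2, a glutathione transferase, by 2.25 (SE 0.21). Syngr1, a vesicle gene (-3.86, SE 0.25), had the smaller value in BAT, and so had the muscle genes Casq1 and Cav3, which were higher in NZO gWAT and at least 27.9-fold and 9.47-fold lower in NZO BAT. Leaving out NZO replicate 009, B6 010 or B6 015 in all tissues gave 1422, 1647 and 1668 genes.

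Between muscle and gWAT, 3740 of 19623 genes differed (1565 larger and 2175 smaller in muscle). Of these, 2789 had fitted differences of opposite signs, passed or not, and 67 genes were called in both tissues with opposite directions. Ifit1bl2 (3.40, SE 0.17), Wnt5b (2.78, SE 0.22) and Klhdc9 (4.68, SE 0.39) had the larger value in muscle, and Pla2g7, a lipoprotein-bound phospholipase (-3.35, SE 0.22), Syngr1 (-3.61, SE 0.25) and Cpt1b (-3.28, SE 0.23) the smaller. Nnt (1.35, SE 0.23, adjusted p = 0.000484) and Ppargc1a (1.41, SE 0.36, adjusted p = 0.00956) also differed. Without NZO replicate 009 or B6 010 in all tissues 2264 and 2454 genes were called, and 1998 with slide as a fixed block. Between BAT and muscle, 809 of 19375 genes differed (386 and 423). Opposite signs of the fitted differences, passed or not, were found for 458, and 16 genes were called in both tissues with opposite directions. Cd28 (3.44, SE 0.31), Tagap1 (1.93, SE 0.18) and Fancl, a DNA repair gene (1.45, SE 0.14), had the larger value in BAT, and Vipr2 (-5.85, SE 0.27), Ifit1bl2 (-3.27, SE 0.17) and Gpx8 (-4.12, SE 0.25) the smaller, as had Nnt (-1.03, SE 0.23, adjusted p = 0.0121). The count of 809 genes was 1252 without B6 muscle replicate 011, 397 without muscle-rich genes (both chosen after the data were seen) and 200 with slide as a fixed block. It was 394, 446, 473 and 523 without NZO replicate 003, B6 010, B6 009 and NZO 009 in all tissues.

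Some genes differed in the same direction wherever they were measured. Of 18985 genes tested in all 3 tissues, 141 were higher and 265 lower in NZO in each, where independent lists of those sizes would share 4.31 and 4.87, and 19 were called in all with opposite directions. Syt10 was higher in gWAT, where 2 B6 arrays were well above background, 32.0-fold in BAT (SE 0.29 log2 units) and 87.3-fold in muscle (SE 0.22), and Tox4 was higher by 5.08, 4.55 and 3.72 log2 units. Another Tox4 probe gave -0.07 in gWAT, -0.18 in BAT and -0.53 in muscle and passed in none, so a strain difference of this gene is open. The histone gene Hist2h2bb and Tescl were also higher in all 3 tissues, each well above background on at most 1 B6 array of any tissue. Acyp2, an acylphosphatase gene, was lower in NZO in all 3, and well above background on 0 NZO arrays of gWAT, 1 of BAT and 2 of muscle. Zfp874a was at least 23.9-fold lower in gWAT and 23.6-fold in BAT, and Apol10b at least 41.6-fold, 19.2-fold and 18.0-fold in the 3 tissues. The same probe stood for the gene in all tissues for all 406 shared genes, so a sequence difference under a probe would recur in each; none was tested for. Without B6 muscle replicate 011, chosen after the data were seen, 617 genes were shared (285 higher), and without B6 replicate 010 in all tissues 253 (80 higher and 173 lower). The higher count was 253 without B6 replicate 011 and 88 without NZO replicate 007 in all tissues.

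**Figure D4:**
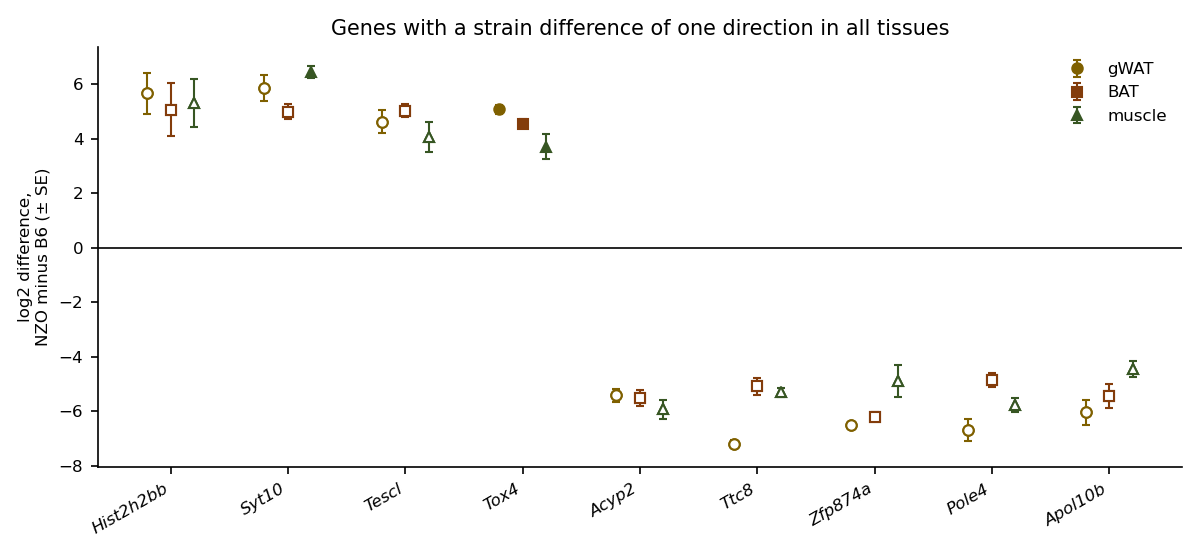
Log2 strain difference, NZO minus B6, with SE in gWAT, BAT and muscle (4 arrays per strain and tissue) for 9 genes that differed in the same direction in all 3 tissues. Open symbols mark genes not well above background on all 4 arrays of each strain, where the value does not measure size. Syt10, Tox4, Hist2h2bb and Tescl lie above 0 and Acyp2, Ttc8, Zfp874a, Pole4 and Apol10b below 0 in each tissue. Another Tox4 probe, not shown, did not pass in any tissue.

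Pairs of tissues shared more called genes than independent lists would. In gWAT and BAT, 752 genes were higher in both (237 for independent lists) and 672 lower in both (206), with 189 opposite. In gWAT and muscle 189 were higher in both (66.5) and 334 lower in both (72.3), with 67 opposite. In BAT and muscle the numbers were 227 (28.0), 322 (37.1) and 16. Mx2 was lower in NZO in each tissue, at least 19.4-fold in gWAT, 10.5-fold in BAT and 5.13-fold in muscle, and Cd22 was higher by 1.93, 1.84 and 1.39 log2 units.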

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

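Chosen only after the result was seen were the test of genes predicted from the median muscle share, the test of the 8 fibre markers on a shared slide, the interval and the values per array of the muscle share, the test of Zic1 and Lhx8, the test of genes alike in both strains' BAT, and the alternatives that left out muscle-rich genes, brown-rich genes or the muscle library B6 011.

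For some values the gap between 1 array and the nearest of the other 3 was large relative to the range of the group, small as some of these gaps were. In muscle the library B6 011 had Ifi202b at 2.30 (next -6.06) and Lep at 3.87 (next -2.92). In B6 gWAT, replicate 015 had the macrophage gene Gpnmb at -0.71 (next -1.61) and the methyltransferase gene Inmt at 3.999 (next 2.63). B6 gWAT replicate 011 had Zfp979 at 1.35 (next 1.47) and 59.01% of probes well above background (next 60.19%), and B6 BAT replicate 009 had Lep at 1.37 (next -0.28). In independent groups of normally distributed values, chance gives such a gap in about 1 in 20. That would be 6.65 of the 133 groups tested, and 7 were found. Many of the genes were chosen for strains that did not overlap, and groups on the same arrays are not independent. These counts therefore do not show whether a given gap arose by chance.

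Strain differences that differed between tissues, each by a test of the difference itself, numbered 2895 for BAT against gWAT, 3740 for muscle against gWAT and 809 for BAT against muscle. For BAT minus gWAT the values were 2.79 for Wnt5b, 4.83 for Klhdc9, 2.25 for Gstm2, -3.86 for Syngr1, -8.70 for Casq1, -6.55 for Cav3 and -8.19 for Ucp1. Those of Casq1 and Cav3 were fitted against NZO BAT arrays not well above background, where only bounds hold (at least 27.9-fold and 9.47-fold lower), so they give a direction and do not measure size. For muscle minus gWAT they were 3.40 for Ifit1bl2, 2.78 for Wnt5b, 4.68 for Klhdc9, -3.35 for Pla2g7, -3.61 for Syngr1, -3.28 for Cpt1b, -10.08 for Ucp1, 1.35 for Nnt and 1.41 for Ppargc1a. For BAT minus muscle they were 3.44 for Cd28, 1.93 for Tagap1, 1.45 for Fancl, -5.85 for Vipr2, -3.27 for Ifit1bl2, -4.12 for Gpx8 and -1.03 for Nnt.

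The muscle library B6 011 held fat transcripts together with Ifi202b, which no other B6 array had at such a level. Of genes well above background in NZO gWAT and not in B6 gWAT or the other B6 muscle libraries, 47.8% (54 of 113) were well above background in it, against 6.49% (5 of 77) of the genes found in B6 gWAT alone, which argued against B6 fat. Genes found in B6 muscle and in no NZO muscle or gWAT array lay at a median position of 0.26 between B6 (0) and NZO (1), which argued against NZO muscle under a B6 label. Fat genes were in it at a median of 29.4% of their NZO gWAT signal (quartiles 26.3% and 32.0%, 77 genes), against at most 1.51% in another muscle library. RNA of NZO fat in this library may therefore be the source, a hypothesis formed and tested on the same data.

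Skeletal muscle transcripts were high in B6 BAT and low in NZO BAT. Of genes at least 5 log2 units higher in B6 muscle than in NZO BAT, 62.2% (166 of 267) were called lower in NZO BAT, which by the bounds set beforehand left muscle tissue in the samples undecided. The share of the muscle signal in B6 BAT had a median of 0.718% over these genes and a robust SD of 0.86 on the log2 scale. Under the bound of 1 set beforehand, that SD taken alone argued against expression by brown fat itself. Resampling the genes, a criterion added after the value was seen, put the SD between 0.73 and 1.09, on both sides of that bound. With this criterion, expression by brown fat itself was not decided either. The share was 1.78% in replicate 010, against 0.361%, 0.561% and 0.597% in 011, 015 and 009 (robust SD 0.72, 1.18, 1.09 and 1.02), and 0.498% over the arrays without 010 (robust SD 0.95). Of genes that the median share predicts to differ by at least 2 log2 units, 87.6% (106 of 121) were called lower, but the share was fitted to the same arrays and genes, so this count does not test the source. On the shared slide these genes differed by a median of 1.63 log2 units, which by the bounds set beforehand did not decide on slide, while the 8 fibre markers differed there by 8.10, between 1 array of each strain. With slide as a fixed block over all arrays, Tnnc2 and Acta1 were still lower by 6.57 and 6.81 (adjusted p = 3.68e-06 and 9.84e-06), which argued against slide as the whole cause for them. With the resampling interval counted, muscle tissue taken with B6 BAT and expression in B6 brown fat itself cannot be told apart. A difference between the strains in the depot stays open.

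Ucp1 and other brown fat transcripts were higher in NZO gWAT. With a share of NZO BAT set by Ucp1, 34 genes richer in NZO BAT than in B6 gWAT lay a median of 0.71 log2 units above the predicted rise (quartiles -0.79 and 1.72). Of them 11 were within 1 unit of it. This choice compares tissues of different strains and so also takes genes higher in NZO in both, such as Ifi202b (predicted 2.35, observed 11.15). Their median therefore does not test brown fat alone. A set of 11 genes alike in both strains' BAT lay a median of 0.53 above the predicted rise. The quartiles were -0.23 and 0.71, the lowest value was -1.67 (Tuba8) and the highest 2.36 (Otop1). On the slides that held both strains the 34 genes gave medians of 2.20 and 2.59 log2 units, which argued against slide. Zic1, which marks the brown depot, lay 0.12 above its predicted level, but that level (-3.10) was close to the one in B6 gWAT (-3.13), and Lhx8 was not well above background on any gWAT array, so neither could separate brown-like cells within gWAT from brown fat in the samples, which cannot be told apart. Either may be the source, and a difference between the strains in gWAT itself stays open.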

How the results depend on the processing

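The alternatives that left out muscle-rich genes, brown-rich genes or the muscle library B6 011, and slide as a fixed block for the gene lists, were chosen only after the result was seen. Of 106 gene, list and shared counts under alternatives other than leaving out arrays, 76 were within 1.5 times the main count and 30 were not, and with single arrays left out 68 of 84 were. Among the named genes 4136 of 4581 values kept direction and side of the threshold, 417 lost their call, 26 gained one and 2 turned, and for the lists 615 of 688 kept theirs. Turned were Nnt in gWAT with probes of a gene averaged (-0.80) and Cidec in BAT with slide as a fixed block (-0.47); the cause was not tested. Signal over background limits what can be said of genes dim in 1 strain, for which folds are given as bounds. The choice of probe is a further limit. Another tested probe existed for 1956 called genes in gWAT, 854 in BAT and 291 in muscle. Another probe was called in the same direction for 63.2%, 54.8% and 47.4% of these, and in the opposite direction for 101, 50 and 18 genes.

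At a threshold of 0.01 the counts were 3503 in gWAT, 1572 in BAT, 460 in muscle, 1195, 1602 and 342 for BAT against gWAT, muscle against gWAT and BAT against muscle, and 193 for the shared genes, a stricter threshold by construction, as is a change of at least 2-fold (2750, 1362 and 681). With an estimated correlation camera called 0 lists in gWAT, 0 in BAT and 0 in muscle, where 3, 4 and 2 lists had an unadjusted p under 0.05, and fry called 13, 12 and 2. Slide as a fixed block gave 1767 genes in BAT, and 1998 and 200 for muscle against gWAT and BAT against muscle; slide as a random block gave 5 lists in muscle, and scan as a fixed block 2061 genes there. Array weights gave 6107 genes in BAT and 4482 in muscle, every probe on its own 1673 in muscle, and all arrays in 1 model 1929. Without the muscle library B6 011 there were 1252 genes for BAT against muscle and 617 shared, and without muscle-rich genes 397 for BAT against muscle. The cause was not tested for these.

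Leaving out each array in turn gave 4765 to 6684 genes in gWAT, 2121 to 3387 in BAT and 607 to 2164 in muscle (671, 654, 607, 2164 and 668 without NZO 003, NZO 007, B6 010, B6 011 and B6 009), and 5 to 12 lists in muscle (5 without B6 011). Leaving out a replicate number of 1 strain in all tissues gave 1422 to 3182 for BAT against gWAT (1422, 1647 and 1668 without NZO 009, B6 010 and B6 015), 2264 to 4025 for muscle against gWAT (2264 and 2454 without NZO 009 and B6 010), 394 to 965 for BAT against muscle (394, 446, 473 and 523 without NZO 003, B6 010, B6 009 and NZO 009) and 253 to 536 shared genes (253 without B6 010).

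A replicate block on the number shared by the strains gave 377 genes in BAT, and in muscle limma called 0 with it (1020 at an unadjusted p under 0.05); samples with unshared numbers carry no weight in such a fit; in gWAT the strains share 1 number, so no such fit was run. A replicate block on strain and number across tissues, as a random effect, gave 1943 genes in muscle. Samples of the same strain and number in different tissues correlated at -0.22 to 0.47 (22 pairs, 9 over 0.1), own numbers were the best partner in 17 of 44 cases, and those of the same tissue and number in different strains at -0.32 to 0.08 (5 pairs), so the numbers do not establish pairing.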

Other observations

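Slide as a fixed block for the lists was chosen only after the result was seen, and the members of lists named here follow the rule for named genes unless said otherwise. In gWAT the p200 family of interferon-inducible genes, next to each other on chromosome 1, split by gene. Of the list 3 of 5 rose in NZO and 2 fell, the same adjusted over the list alone. Ifi202b was at least 531-fold higher and Mndal lower by 5.59 log2 units (SE 0.29). This list passed with slide as a random block and with fry (adjusted p = 1.51e-05 and 3.33e-05; adjusted p = 0.985 with an estimated correlation). In BAT 2 of 4 rose and 2 fell, again the same over the list alone, with Mndal lower and well above background on 1 NZO array, and the list passed in the same settings (0.00114 and 0.000759; adjusted p = 0.984 with an estimated correlation). Interferon response genes went 2 up and 1 down of 21 in gWAT and 5 up and 1 down of 21 in BAT, the same adjusted over the list alone, and the antiviral genes Mx1 and Mx2 moved apart in gWAT, at 2.95 (SE 0.32) and at least 19.4-fold lower. Neutrophil markers had 4 higher and 1 lower of 6 in gWAT, the same over the list alone, with S100a8, a calprotectin subunit, 22.8-fold higher and Ly6g at least 5.59-fold lower, and passed with fry (adjusted p = 0.0330; adjusted p = 0.969 with an estimated correlation).

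Circadian clock genes in gWAT had 5 lower and 0 higher of 15, the same adjusted over the list alone, among them Cry2 (-0.80, SE 0.12) and Nr1d1 (-1.65, SE 0.34); camera's adjusted p for the list was 0.0599 (adjusted p = 0.576 with an estimated correlation). It was 0.0379, 0.0239 and 0.0374 without B6 replicate 010, 011 and 015, 0.0287 with normexp, 0.0208 with slide as a fixed block and 0.00469 with fry. Adipokine genes had 4 higher and 5 lower of 11 in gWAT, with the Wnt inhibitor gene Sfrp5 9.01-fold higher, and 4 higher and 1 lower of 11 in BAT, with the resistin gene Retn lower (-1.55, SE 0.17); both counts were the same over the list alone. Antioxidant genes had 4 higher and 6 lower of 22 in gWAT (5 and 8 adjusted over the list alone) and 3 and 5 of 22 in BAT (4 and 7), with the glutathione transferase gene Gstm2 at -2.53 (SE 0.14) in gWAT and -2.22 (SE 0.17) in muscle and the peroxiredoxin gene Prdx3 at -1.01 (SE 0.10) in BAT. The antioxidant list passed in gWAT under quantile normalization, with slide as a random block and with fry (adjusted p = 0.0310, 0.0271 and 0.0497; adjusted p = 0.985 with an estimated correlation) and in BAT with fry (0.00369; adjusted p = 0.484 with an estimated correlation). Schwann cell markers had 1 higher and 2 lower of 5 in gWAT, the same over the list alone, with S100b at 2.51. The level of S100b was also high in NZO BAT (6.10), so its rise in gWAT need not mark Schwann cells.

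In each tissue only the real one of 35 splits of the 8 arrays into 4 and 4 gave as many called genes. The counts were 6762 in gWAT (highest other 1), 3138 in BAT (highest other 3) and 1072 in muscle (highest other 1). That is the smallest share that 35 splits can give, and every other split moves the strain difference into the spread within groups. It argued against chance for these counts but does not exclude it. For the number of lists called, 23 of 35 splits in gWAT, 10 in BAT and 30 in muscle gave at least the real 8 (highest other 15, 16 and 19), so chance is not excluded for the list counts. Of 100 regroupings of the strains within tissues, the real one included, 2 gave as many genes for BAT against gWAT (2895, highest other 3499, in a draw that kept the 4 NZO gWAT arrays together), 1 for muscle against gWAT (3740, highest other 2407), and 1 for BAT against muscle (809, highest other 485). Draws that kept the real groups of gWAT alone gave 1559, 2666, 1587, 1637 and 3499 for BAT against gWAT. The draws remove the strain effect from the tissues they regroup and so do not test an equal strain effect in 2 tissues, and chance is not excluded by them for these counts. For the shared genes it was 1 (406, highest other 0), but no other draw kept the real groups of more than 1 tissue, so these draws do not test sharing.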
